A study of Dicentrarchus labrax with 10 samples.

How the data were processed

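RNA from gonads of 10 European sea bass, 5 per early rearing temperature, was measured on 1-colour arrays. Per the labels' protocols, total RNA with an integrity number above 7 was used, and 100 ng was amplified and labelled with Cy3 together with Agilent's 1-colour spike-in RNA. The deposited scanner files hold intensities that Agilent Feature Extraction 10.7.3.1 made from each scanned array, per the file headers, and the submitters' processing notes name Agilent Feature Extraction and limma without versions. Per the file headers, the processed intensity is background-subtracted and corrected for spatial trends within the array, and from the values it is not normalized between arrays. The authors' deposited value table holds 21701 non-control probes on a log2 scale. How it was made is not given in the sources used here. Its columns correlated at 0.984 to 1.00 with the log2 of the median spot intensity without background subtraction and at 0.930 to 0.963 with the log2 of the processed intensity, and their medians lay between 8.01 and 8.05, so the scale and direction follow from the values and the exact normalization stays unknown.

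From the scanner files, spots flagged as outliers were left out (1057 non-control spots over all arrays, 762 of them on the slide of replicate 1), as were the 1417 control spots per array. No non-control spot was saturated. The log2 processed intensity minus each array's 75th percentile over non-control spots was used, and spots of the same probe were averaged (18825 probes were spotted in duplicate, 5321 once and 54 were spotted 15 or 16 times). A probe was kept when at least 50% of its spots were well above background on at least 5 of the 10 arrays, which kept 20115 and left out 4085. Probes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, group as the only term, and called at a Benjamini-Hochberg adjusted p under 0.05. For transcripts, the probe with the highest mean signal over all arrays was taken. Array measures and component scores were compared with exact permutation tests over 252 assignments, which ignore the slide. Figures were drawn with matplotlib 3.10.9. Replicates are individual fish, and their number limits the precision. In simulated data with the real means and spreads of 19927 probes, 200 of them changed, the fit recovered 78% of 4-fold and 21% of 2-fold changes with 4 false calls and none of the wrong sign. The simulated probes were drawn independently of each other, without effects of slide, brightness or fish shared between probes. These rates therefore need not hold for the real data.

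The test, the filter, the rule for named genes and the gene lists were fixed before the data were examined, as were most alternatives. Probes carry contig and clone names, and no gene symbols were used here, and the files do not pair probes with genes, so the gene lists could not be matched, and the tests of lists and of list scores were not made. The rule for named genes was a set of fixed genes, list members, and the 10 largest rises and falls past the threshold with the same sign on at least 4 of 5 slides. The rule left out clone and contig names. As no gene names were used, its ranking was applied to these names all the same, a departure made after the files were seen, and only the 2 largest in each direction are named. Normexp correction was run on the median spot and median background intensity with an offset of 50, because the mean spot intensity planned for it is not a column of these files. Alternatives were the slide as a fixed replicate block or a random block, quantile normalization, other percentiles and centring, spike-in scaling over 7 of the 10 E1A spike-in probes, other filters, the authors' table, moderated variance with a trend, array weights, brightness as a covariate and leaving out single fish.

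The slide and the place of each array on it were read from the file headers. Arrays with the same replicate number shared a slide and a scan. All LTE2 arrays lay at place 3 and all HTE2 arrays at place 4 of their slide, so that place and group cannot be told apart. The slide entered as a batch and not as a pairing of fish. No 2 arrays were alike, with a largest probe difference of at least 5.64 log2 units in every pair.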

Results

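The gonadal transcriptome was measured in 10 individual European sea bass (Dicentrarchus labrax), a fish whose sex depends on both its genes and the temperature of early life. Larvae of both groups were kept at 17 °C up to 20 days post hatch (dph). One tank was then brought to 21 °C (high temperature) and the other to 15 °C (low temperature) until 60 dph, after which the low temperature group was raised to 21 °C as well. Both groups received food carrying estradiol, a feminizing estrogen, from 90 to 154 dph, and the gonads were sampled at 170 dph from fish labelled as putative females. The 5 fish of the early high temperature group are called HTE2 here and the 5 fish of the early low temperature group LTE2. The design poses 1 question, whether the gonads of estradiol-fed fish at 170 dph differ in gene expression with the rearing temperature of early life. Each temperature was held in 1 tank, so that tank and temperature cannot be told apart, and no fish without estradiol was analysed here.

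Each fish was hybridised to its own 1-colour Agilent oligonucleotide array with 24200 distinct probes for 11705 transcripts. Each transcript carries the name of an assembled contig or of a cDNA clone, and transcripts are given here by those names only, without gene symbols or positions in the genome. The arrays differed in brightness. The 75th percentile of the processed intensity ranged from 232.8 in LTE2 replicate 1 to 1392 in HTE2 replicate 4, and its mean was 525.1 ± 174.2 (SD, n = 5) in LTE2 and 936.3 ± 304.3 (SD, n = 5) in HTE2. The HTE2 array was the brighter of the pair on all 5 slides. The group means of the log2 values differed in a test that ignored the slide (exact permutation test, two-sided p = 0.0159, 0.0397 after Benjamini-Hochberg adjustment over 5 array measures). Splits that keep 1 array of each slide in each group cannot give a share below 0.0625. Between 17692 and 20848 probes per array were well above background, 19095 ± 999 in LTE2 and 20378 ± 565 in HTE2 (SD, n = 5; exact permutation p = 0.0397, adjusted 0.0661). Among kept probes spotted 15 or 16 times, the repeated spots of a probe within an array had a median SD of 0.09 to 0.14 log2 units. Over all kept probes the median SD between fish of a group was 0.47 log2 units. As each fish had its own array, the value of 0.47 also holds differences between arrays.

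HTE2 and LTE2 gonads differed at many probes in both directions. Of 20115 probes that passed the detection filter, 5584 (27.8%) differed between HTE2 and LTE2 at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 2811 higher and 2773 lower in HTE2. With 1 probe per transcript, 2511 of 9929 transcripts differed, 1067 higher and 1444 lower in HTE2. Among the called probes the median rise was 2.44-fold and the median fall 2.18-fold. The balance of larger changes depended on their size. Over 4-fold, 466 probes were higher and 172 lower (Fisher's exact test among the called probes, p = 4.5e-35, with probes that are not independent of each other), and 163 transcripts were higher and 89 lower. Over 2-fold, 744 transcripts were higher and 925 lower, against 2020 and 1760 probes. Beyond 8-fold, 15 probes were higher and 25 lower, and 5 transcripts were higher and 13 lower. Of the probes tested, 2761 (13.7%) had no overlap between the 5 values of one group and the 5 of the other, 968 of them higher and 1793 lower in HTE2, where chance gives 0.794%.

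These counts depended on single fish and on how the slide was modelled. Each of the 5 slides held 1 array of each group with the same replicate number. With the slide as a fixed replicate block 3182 probes were called, 1469 higher and 1713 lower. Of these, 2967 were among those called without the block. With the slide as a random block 5704 probes were called, 2856 higher and 2848 lower, at an estimated within-slide correlation of 0.0127. Leaving out 1 fish at a time gave 2695 probes without LTE2 replicate 4, 2730 without LTE2 replicate 5, 2905 without HTE2 replicate 1, 3198 without HTE2 replicate 2, 3656 without HTE2 replicate 4, 3614 without HTE2 replicate 5 and 8737 without HTE2 replicate 3. The split into higher and lower is relative to the 75th percentile of each array. On that scale the median difference of all probes, HTE2 minus LTE2, was -0.18 log2 units. In alternatives chosen after seeing the data, scaling to the added spike-in RNA instead moved that median to 0.87 and the calls to 3287 higher and 30 lower. Normexp background correction moved the median to -0.47 and the calls to 1190 higher and 2446 lower. With array brightness as a covariate, 105 probes were called, 13 higher and 92 lower.

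**Figure D1:**
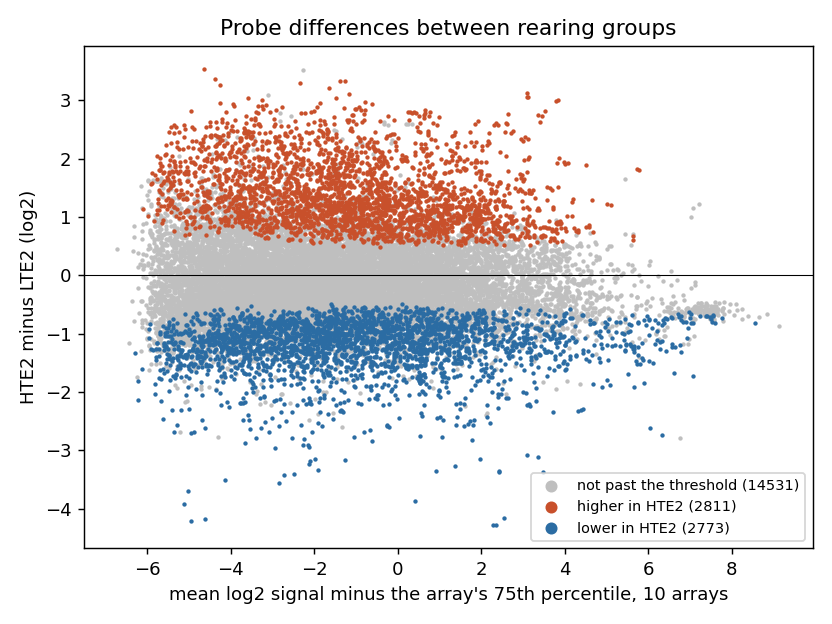
Difference between the group means (HTE2 minus LTE2, log2) against the mean log2 signal over the 10 arrays, relative to each array's 75th percentile, for the 20115 probes tested, 1 point per probe. Probes past the threshold are coloured, 2811 higher and 2773 lower in HTE2, and the grey group near 7 on the x axis lies below 0.

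Probes for the same transcript gave like answers. Of 4855 transcripts with 3 or more tested probes, 4392 (90.5%) had all probes on the same side of 0, and the median SD of the log2 fold between probes of a transcript was 0.06. Where at least 1 probe was called, all probes shared the direction in 1709 of 1743 transcripts (98.0%), and 1103 transcripts had every probe called in the same direction. Only 1 transcript of the 4855 had called probes in both directions. Calls were spread over the range of abundance, from 22.2% of probes in the lowest quartile of mean signal to 32.8% in the highest, and the share of calls that were higher in HTE2 lay between 47.2% and 54.1% in the 4 quartiles.

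With 1 probe per transcript, the largest rises among called transcripts were those of the clones cDN27P0002C12 and cDN23P0004K04. The transcript cDN27P0002C12 rose 8.59-fold in HTE2, from -2.71 ± 1.08 to 0.39 ± 1.38 log2 units relative to the 75th percentile (SD, n = 5; log2 difference 3.1, SE 0.67, limma adjusted p = 0.0136). Its other 2 probes gave 3.34 each. The transcript cDN23P0004K04 rose 8.30-fold, from 1.60 ± 0.76 to 4.65 ± 1.41 (SD, n = 5; log2 difference 3.05, SE 0.62, limma adjusted p = 0.0123), with 3.05 and 3.13 in its other probes. Neither rise was present on the slide of replicate 3, where HTE2 minus LTE2 was -0.59 for cDN27P0002C12 and -0.56 for cDN23P0004K04. On the other 4 slides the differences lay between 2.70 and 5.30 for cDN27P0002C12 and between 3.29 and 4.44 for cDN23P0004K04. Both transcripts passed with the replicate block (limma adjusted p = 0.0439 and 0.0415), but not in the authors' value table with the block (0.0616 and 0.0528). With array brightness as a covariate the log2 differences stayed at 3.04 and 3.04 while their SE rose to 0.94 and 0.86, and neither passed (limma adjusted p = 0.114 and 0.102). The size of the rise of cDN27P0002C12 depended on the processing, with a log2 difference of 1.95 under normexp, 2.09 in the authors' value table, 4.15 under spike-in scaling and 4.03 without slide 3, and that of cDN23P0004K04 was 4.1 under spike-in scaling, 3.67 without HTE2 replicate 3 and 3.96 without slide 3.

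On the same basis the largest falls were those of cDN22P0005J11 and cDN27P0002C01, and they held on all 5 slides. The transcript cDN22P0005J11 fell 18.0-fold, from 4.64 ± 0.40 in LTE2 to 0.47 ± 1.08 in HTE2 (SD, n = 5; log2 difference -4.17, SE 0.46, limma adjusted p = 0.000806), and its other probes gave -4.28 and -4.29. The slide differences of cDN22P0005J11 ranged from -5.39 to -2.94. The transcript cDN27P0002C01 fell 14.6-fold at its brightest probe, from 2.35 ± 0.30 to -1.51 ± 0.40 (SD, n = 5; log2 difference -3.86, SE 0.24, limma adjusted p = 1.6e-05), with slide differences of cDN27P0002C01 between -4.52 and -3.12. Its other 2 probes gave -0.71 and -0.68, so that the size of the fall of cDN27P0002C01 rests on 1 probe, and the mean of its probes was -1.75. Both falls passed with the replicate block (limma adjusted p = 0.00682 and 0.00465). Under spike-in scaling the log2 differences of cDN22P0005J11 and cDN27P0002C01 were -3.12 and -2.82, and cDN27P0002C01 stood at -3.25 in the authors' value table.

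**Figure D2:**
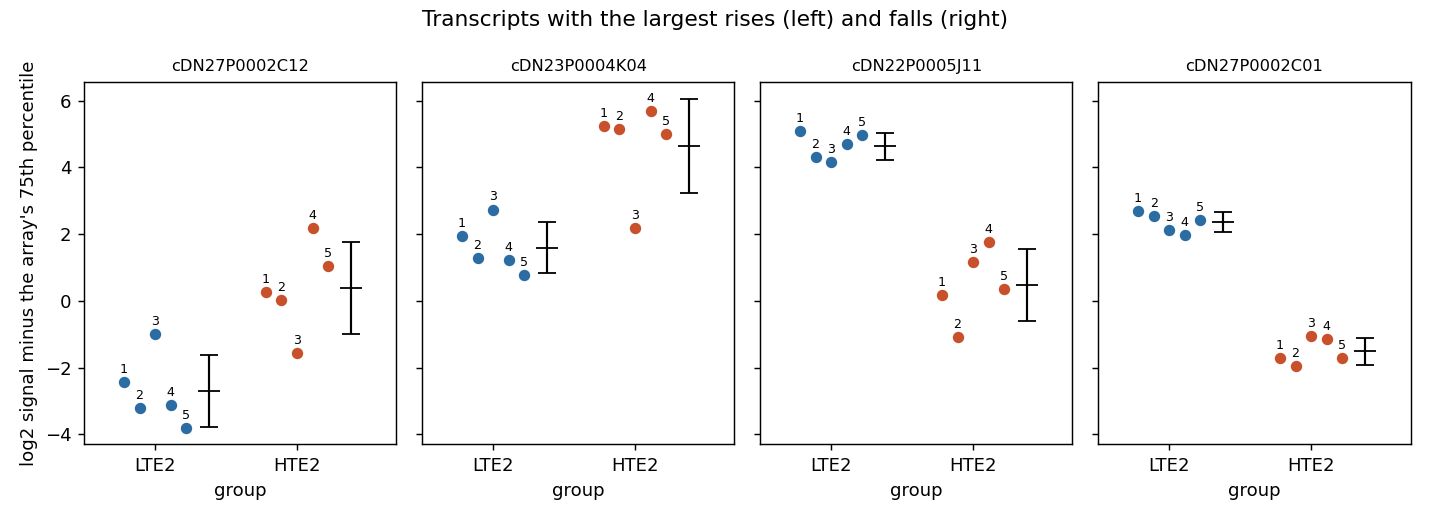
Log2 signal relative to the array's 75th percentile in each fish for the 2 transcripts with the largest rises and the 2 with the largest falls, with the replicate number above each point and the group mean ± SD (n = 5) as a bar beside the points. In cDN23P0004K04 the HTE2 fish of replicate 3 lies at 2.18, apart from the other HTE2 fish, while in cDN22P0005J11 and cDN27P0002C01 all HTE2 fish lie below all LTE2 fish.

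A small set of probes was well above background in 1 group only. Well above background on all 5 HTE2 arrays and on no LTE2 array were 70 probes of 66 transcripts, of which 52 probes were called higher. Their median measured difference was 1.60 log2 units. As they were chosen for being detected in HTE2 only, their calls are no separate evidence. The other probes of these transcripts were not checked, so absence of the transcripts from LTE2 is not shown. The reverse held for 2 probes of 1 transcript, both called lower. The HTE2 arrays were also the brighter ones and had more probes above background, as given above. On all 10 arrays 16693 probes were well above background, and 1778 were so on none.

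Fish differed in how far they followed the group difference. The first principal component took 52.5% of the variance and separated the groups completely, with scores of -61.8 ± 24.1 in LTE2 and 61.8 ± 61.1 in HTE2 (SD, n = 5; exact permutation test, two-sided p = 0.00794, the smallest that 5 against 5 can give, 0.0238 after Benjamini-Hochberg adjustment over 3 measures). Within HTE2 the scores ran from -20.3 in replicate 3 to 152.2 in replicate 4, and within LTE2 from -84.1 in replicate 2 to -23.8 in replicate 3. The second component, with 16.1% of the variance, did not separate the groups (exact permutation p = 0.722). The root mean square log2 distance over probes between a fish and another of its group, averaged for each fish, was 0.85 ± 0.08 in LTE2 and 0.92 ± 0.16 in HTE2 (SD, n = 5), a difference that did not pass the test (exact permutation p = 0.397). HTE2 replicate 3 was the only fish whose expression correlated better with the other group (mean r = 0.947 across probes) than with its own (mean r = 0.918).

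**Figure D3:**
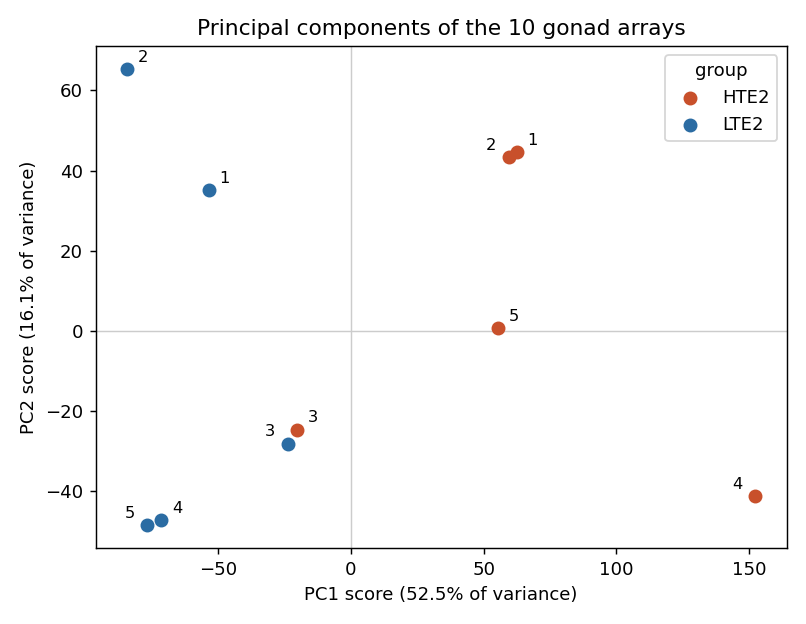
Scores of the 10 arrays on the first and second principal components of 19927 probes measured on every array, with the share of variance on each axis, points coloured by group and marked with the replicate number. All HTE2 fish lie to the right of all LTE2 fish, and replicate 3 of both groups lies close together at -20.3 and -23.8 on the first component.

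The group difference was taken on each slide separately and set against the fold from the other 4 slides, over the probes called without that slide among the 19927 measured on every array. On slides 1, 2, 4 and 5 the slope was 0.825, 0.972, 1.26 and 1.03 (jackknife SE 0.130, 0.0937, 0.105 and 0.0842). On these slides 95.1% to 98.5% of the called probes had the same sign, over 808, 349, 664 and 200 probes. On slide 3 the slope was 0.0140 (SE 0.00948), and 51.7% of 7892 called probes had the same sign. The larger set of slide 3 holds weaker probes too, so the shares are not over like probes. The fold set against slides 1, 2, 4 and 5 includes slide 3, which makes that fold smaller. Over all 20115 probes tested, 7928 were called without both arrays of slide 3, 3840 higher and 4088 lower.

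**Figure D4:**
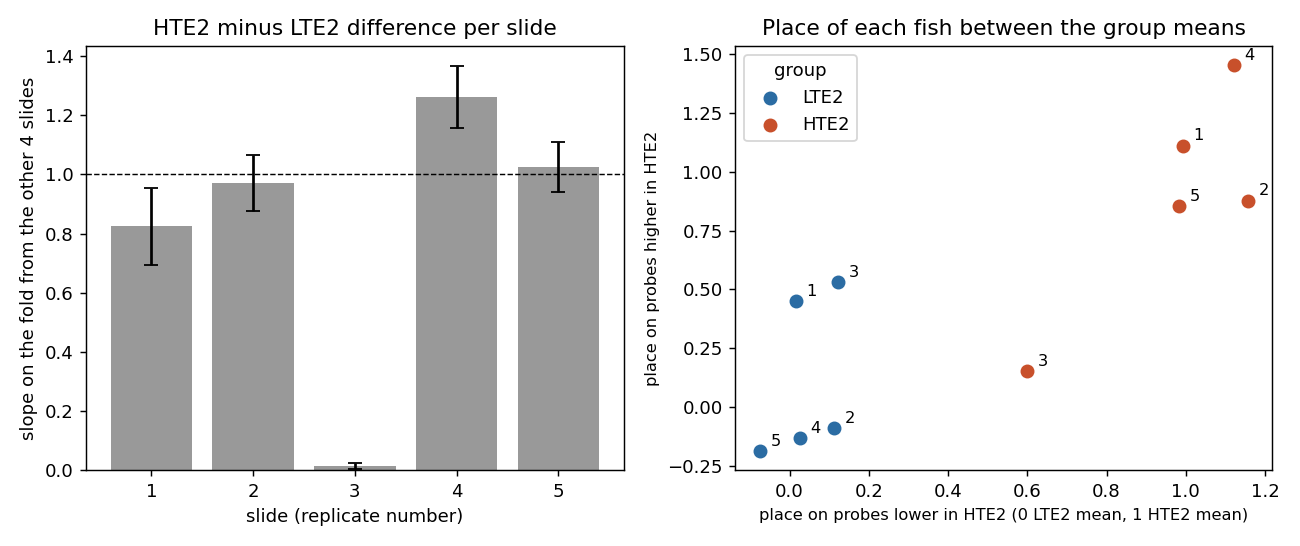
Left panel, slope of each slide's HTE2 minus LTE2 difference on the fold from the other 4 slides, with the jackknife SE over arrays as error bars and a dashed line at 1. Right panel, median place of each fish between the LTE2 mean (0) and the HTE2 mean (1) over up to 100 probes with the smallest p in each direction, in the fit without that fish, where HTE2 replicate 3 stands at 0.599 on the lower probes and 0.154 on the higher ones, against 0.270 and 0.195 over the 4638 lower and 3992 higher probes called without it among the 19927 measured on every array.

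The authors' deposited value table was put through the same limma fit. Of its 21701 probes, 5209 were called, 2891 higher and 2318 lower in HTE2. Of 5540 probes called from the scanner intensities and present in that table, 4554 were called there too, all in the same direction, and the log2 folds correlated at r = 0.911 across 19907 probes, which are not independent replicates. With the replicate block, the authors' table gave 638 calls, 142 higher and 496 lower.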

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

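The tests of array place, of an additive slide effect and of a wrong label were chosen after the results they concern had been seen, and the criteria for an additive slide effect, swapped labels, a wrong label and mixed RNA were changed after their values were seen. For swapped labels neither bound written beforehand was met, and the size that a swap would keep was used instead. For mixed RNA the bound written beforehand was kept, and known mixtures were added to judge it. In 24 groups of 5 values, screened for a fish far from the others of its group, chance alone picks about 1 group in 20. LTE2 replicate 1 had a log2 75th percentile of 7.86, far below the next LTE2 array at 9.0. HTE2 replicate 3 had a value of 2.18 for the transcript cDN23P0004K04, far below the next HTE2 fish at 5.00.

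Of 100 splits of the arrays into 5 and 5, 1, the real one, gave as many as 5584 called probes, and 1 gave as many as 2511 transcripts, so chance can be excluded for splits that ignore the slide; the highest of the others gave 4625 and 1795, exchanging the fish of replicate 3, and only 16 splits keep 1 array of each slide in each group, too few for a share under 0.05. With array brightness as a covariate, the folds of the called probes kept a slope of 0.950 (jackknife SE 0.202) on their folds without it. These probes were called on the same arrays for little spread within groups, which favours a slope near 1. Only 105 probes still passed, as the median absolute log2 fold went from 1.19 to 1.08 and its median SE rose from 0.31 to 0.41. The log2 brightness difference (HTE2 minus LTE2) was 1.69, 0.836, 0.672, 1.03 and 0.104 on slides 1 to 5. The slopes on the fold from the other slides were 0.825, 0.972, 0.0140, 1.26 and 1.03. The group difference thus did not follow brightness from slide to slide, which argues against brightness as the whole cause. The place on the slide and the rearing tank each coincide with the group, so the design does not separate them from temperature. A place effect of the same size on every slide would give slide 3 a slope like that of the other slides. The slope of 0.0140 there argues against such an effect as the whole cause, though it rests on the 2 arrays of slide 3. A place effect that differs between slides and an effect of the tank stay open. An effect of early temperature stays open beside them.

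On slide 3 the HTE2 and LTE2 arrays differed little along the group difference; an additive slide effect would shift both alike and cancel in their difference, so it does not account for a slope of 0.0140 against 0.825 to 1.26 on the other slides. Swapped labels would turn the sign and keep the size, with a slope of -1.26 to -0.82 as the other slides have it, so they do not account for 0.0140 (jackknife SE 0.00948), though a slope so near 0 cannot show which array is which. A wrong label on HTE2 replicate 3 stays open. Over the 4638 probes called lower without it, among the 19927 measured on every array, its median place was 0.270. That lay above the LTE2 fish (-0.05 to 0.215, mean 0.0962, SD 0.115, n = 5) by less than 3 SD, and far below the other HTE2 fish (0.852 to 1.68). Over the 100 lower probes with the smallest p its place was 0.599. This lay above all LTE2 fish (-0.0755 to 0.123) and below the other HTE2 fish (0.982 to 1.16). Over the 100 higher probes with the smallest p its place was 0.154, within the LTE2 fish (-0.186 to 0.530), so the 2 directions did not place it alike. Mixed RNA would give 1 share of HTE2 from higher and lower probes, and the shares differed by -0.332 (jackknife SE 0.0421), past the bound set beforehand (over 0.2 and over 2 SE); that bound was also met by 2 of 12 known mixtures, both of slide 2 (-0.315, SE 0.0557, and -0.218, SE 0.0565), made from the 2 arrays of each other slide at HTE2 shares of 0.25, 0.5 and 0.75 over as many probes (3835 higher, 4057 lower), so it does not exclude mixing, although -0.332 lay below all 12 and, with 500 and 100 probes per direction, -0.569 (SE 0.0285) and -0.729 (SE 0.0197) lay far below the lowest mixtures (-0.297 and -0.307). The mixtures were read on the probes with the smallest p in each direction, called or not. Without slide 2, only 42 higher and 307 lower probes were called. LTE2 replicate 2 unmixed gave -0.397 (SE 0.116) over as many probes, so the 2 mixtures of slide 2 may carry that fish's own deviation. The comparison is thus a weak guide to what mixing gives on slide 3. Differences between individual fish in gonad state may also account for the pattern and were not tested.

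Of 221 probes with a mean over 6 log2 units above the 75th percentile, 55 were called lower and 0 higher by limma (12 lower with the replicate block), with a median log2 difference of -0.65, and of 0.03 before scaling. Under quantile normalization 2 of them were called lower and 1 higher, and the authors' values gave 7 lower and 15 higher. A plateau of the brightest spots could give this on the brighter arrays. The median of these probes followed log2 brightness with a slope of 0.0022 (jackknife SE 0.650, group as a term), too wide to decide, so scaling and expression cannot be told apart for these probes.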

How the results depend on the processing

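Normexp on the median spot intensity, spike-in scaling, median centring, the brightness covariate, the fits without slide 3 and the block on other values were chosen after seeing the data. With the replicate block, 3182 probes and 1484 transcripts were called, with the block on quantile-normalized values 3711 and 1632, and with the block on the authors' values 638 probes and 482 transcripts. Arrays of a slide deviated from their group means with correlations of 0.380, 0.292, -0.322, 0.0303 and 0.165 on slides 1 to 5, and only slides 1, 2 and 5 held each other's best partner. The value on slide 3 follows from the small difference between its 2 arrays. These correlations do not show whether the numbers pair the fish. Array weights gave 10288 probes and 4818 transcripts, an adjusted p under 0.1 gave 8432 and 3915, normexp gave 3636 probes, spike-in scaling 3317 and 1243, and the brightness covariate 105 and 61. Except where the construction shows it (a looser threshold, a wider SE with the covariate), the cause was not tested. The fixed block leaves fewer residual degrees of freedom, but how far this lowered the calls was not tested. With the slide as a random block, 5704 probes and 2610 transcripts were called. Leaving out 1 fish at a time gave 2695 to 8737 probes and 1099 to 4108 transcripts, with transcripts moved by over 1.5 times without LTE2 replicates 4 (1099) and 5 (1180) and HTE2 replicates 1 (1194), 2 (1346), 3 (4108), 4 (1633) and 5 (1462). All other alternatives run stayed within 1.5 times of 5584 probes and 2511 transcripts, and the share of probe calls higher in HTE2 moved by over 10 percentage points from 50.3% under normexp (32.7%), spike-in scaling (99.1%), the brightness covariate (12.4%) and the authors' table with the block (22.3%). The falls of cDN22P0005J11 and cDN27P0002C01 passed under all 27 alternatives, with highest adjusted p of 0.0239 and 0.00813 (limma) and log2 differences of -4.64 to -3.12 and -4.04 to -1.75. The rises of cDN27P0002C12 and cDN23P0004K04 kept their sign under all 27, with log2 differences of 1.95 to 4.15 and 2.80 to 4.1, and missed the threshold in 2, the brightness covariate (log2 3.04 in both, with a wider SE, adjusted p = 0.114 and 0.102) and the authors' table with the block (adjusted p = 0.0616 and 0.0528, limma). The first component separated the groups with the smallest possible exact permutation p under quantile normalization and with probes above background on all 10 arrays. Normexp on the mean spot intensity and the tests of gene lists and list scores were not run. As a limit of signal over background, 1778 probes were above background on no array, and nothing can be said from those probes.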

Other observations

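Transcripts known from different cDNA libraries differed in the direction of their calls, taken relative to the 75th percentile of each array. The test of directions on slide 3 was chosen after its result was seen, its criterion was extended to centred shares and to transcripts later, and it was changed from the 500 probes with the smallest p per direction to all called probes. Clone names begin with a library number from 22 to 35, and the tissue behind each number is not given in the sources used here. Among 6767 transcripts named by a single clone, 636 were called higher and 1022 lower in HTE2. Clones of library 23 were called higher in 91 and lower in 24 cases (79.1% higher), those of library 24 in 62 and 21 (74.7%) and those of library 22 in 55 and 24 (69.6%). Clones of library 28 went the other way, with 31 higher and 139 lower (18.2% higher), as did library 33 with 38 and 123 (23.6%) and library 27 with 50 and 124 (28.7%). Each of these 6 differed from the other libraries together (Fisher's exact test, Benjamini-Hochberg adjusted p from 4.1e-19 to 0.0150 over 14 libraries), and the 8 others did not pass. Over all 14 libraries the direction of the call depended on the library (Fisher-Freeman-Halton permutation test, p = 1e-05, the smallest that 100000 simulated tables can give, on transcripts that are not independent). Under quantile normalization libraries 22, 23 and 24 had 74.7%, 81.0% and 79.3% of calls higher and library 28 had 22.8%, and without slide 3 they had 63.3%, 83.1%, 72.1% and 17.6%. The libraries were not compared on other scales. Over all transcripts, spike-in scaling gave 1226 called higher and 17 lower, and normexp 561 and 1596. Opposite directions of the libraries are therefore not shown on every scale.

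Whether probes higher and lower in HTE2 were held unequally on slide 3 stayed undecided, as over all called probes the gap between them depended on centring. Among the 19927 probes measured on every array, 65.0% of the 4057 called lower without this slide were lower on it as well, and 37.5% of the 3835 called higher were higher, a difference of 27.6 percentage points. Centring the slide on its median of -0.07 left 58.5% and 44.2%, 14.3 points apart. With 1 probe per transcript, 1378 of 2208 lower transcripts (62.4%) and 591 of 1464 higher ones (40.4%) kept their sign, a gap that fell to 8.71 points after centring. A gap over 20 points was to count for unequal directions and one under 10 against them; the centred gap of probes lay between these bounds and that of transcripts below them. The gap was wider among probes with the smallest p, with 442 of 500 lower probes (88.4%) and 90 of 500 higher ones (18.0%) keeping their sign, or 85.8% and 25.4% after centring. Over the lower probes called without each fish, the median places between the LTE2 mean (0) and the HTE2 mean (1) were -0.05 to 0.215 for LTE2 fish, 0.270 for HTE2 replicate 3 and 0.852 to 1.68 for the other HTE2 fish. Over the higher probes they were -0.22 to 0.429, 0.195 and 0.958 to 1.57. The contrast rests on the 2 arrays of slide 3, 1 fish of each group, and LTE2 replicate 3 stood at 0.215 on the lower and 0.429 on the higher probes.

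The added spike-in RNA showed no group difference past the threshold. Its mean log2 intensity was 9.89 ± 0.30 in LTE2 and 9.71 ± 0.89 in HTE2 (SD, n = 5; exact permutation p = 0.675). The 75th percentile relative to the spike-in was -0.95 ± 0.60 in LTE2 and 0.10 ± 1.2 in HTE2 (SD, n = 5; exact permutation p = 0.127), and within HTE2 it ran from -1.43 in replicate 5 to 1.27 in replicate 4.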
